A study of Bos taurus with 7 samples.

How the data were processed

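Total RNA from commercial, skimmed and filtered cow's milk (Bos taurus) and from milk fractions was measured by small RNA sequencing. Per the labels, the libraries held inserts of about 8 to 35 nt and were sequenced for 51 cycles. There were 7 libraries, 3 of milk and 1 each of the fractions titled MP 12k, 35k, 70k and 100k, where the labels do not spell out MP or k. Nothing in the labels says that the milk libraries came from separate cows or cartons, so every p-value here measured only the spread between these libraries, which may be technical.

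Per the file headers, the authors listed each distinct sequence of 8 to 15 nt with its read count. Beside it stood its RPM, the reads scaled by the authors to a common total of the 8 to 15 nt reads, per the file headers. The deposited RPM values equalled read counts divided by the file total, to within 0.0005. The same held for the RPM column of milk 1, whose other deposited value, a closing total, doubled the column sum. Each file ended with 1 total without a sequence, which repeated the sum of all reads and was left out. Read trimming, collapsing, any filter, the aligner and the genome build are not given in the sources used here. The totals are those of the 8 to 15 nt window and not the depth of the whole libraries, whose totals are not given in the sources used here.

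The totals were 1658606, 3070812 and 4572650 reads in the milk libraries and 2309731, 2560280, 1817538 and 1938689 reads in the 12k, 35k, 70k and 100k fractions. A count of 0 allowed up to 3 reads, which is 0.656 to 1.81 RPM depending on the library. Shares of reads had 95% Wilson intervals of at most 0.0754 percentage points on either side. The reads carry no molecular identifiers, so intervals and limits cover counting error only.

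No genome was used. RNAs were identified by exact match, on their own strand, of reads of at least 12 nt to a list of 108 RNA sequences entered by hand before the data were examined. The list came from general knowledge of vertebrate RNAs and was not checked against a bovine genome. It held 84 mature microRNAs in 5 lists (46 broadly expressed, 22 epithelial and mammary, 7 leukocyte, 3 erythrocyte, 6 of other tissues), 6 transfer RNAs (tRNAs), 5 ribosomal RNA (rRNA) pieces, 2 Y RNAs, 4 small nuclear and 7SL RNAs, and as controls 4 plant microRNAs and 3 kit adapters. Related members were summed to 72 families, called parent RNAs below. Reads that fitted several families were ambiguous. Matching each read backwards, as a measure of chance, gave at most 1.03 RPM in any class of this list. After the most abundant unmatched sequences had been seen, 29 segments were added, 17 of animal rRNA and tRNA and 12 of bacterial RNA. They entered a named alternative and the naming of sequences, not the tests of parent RNAs. Backward matches to the longer list reached 11.6 RPM for rRNA, 3.12 RPM for tRNA and 1.56 RPM for bacterial RNA.

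Sequences with at least 10 reads in at least 3 libraries were tested, 5681 in all, holding 85.5% to 93.7% of the reads of a library. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts with TMM factors and Benjamini-Hochberg adjustment at 0.05. It compared the 4 fractions, taken as libraries of 1 kind, with the 3 milk libraries. A model with 5 group means compared each fraction with milk. There the fraction had 1 library, the spread came from the milk libraries, and the fraction was assumed to vary like them. Parent RNAs were tested in the same way on summed reads, with library sizes from the file totals and no TMM. The test of parent RNAs for each single fraction was added after the data were seen. Shares of reads per length, first base, RNA class and abundance rank were compared by exact permutation tests, two-sided, over the 35 splits of 3 against 4 libraries. The smallest p that these allow is 0.0571, so none could pass 0.05. Sharing of sequences and Spearman correlations across sequences were described without a test.

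The sequences named in the text followed a rule fixed before the data were examined. It took the 10 sequences with the highest mean RPM in milk, the 3 with the most reads in each fraction, and the called sequences with all fractions on 1 side of all milk libraries, with at most 8 per direction. It also took every called parent RNA and the 5 most abundant parents of each class, ranked here by their milk mean. Sequences that contained a named one counted as its variant. Another 12 sequences were chosen after their values were seen and are marked as such where they appear. Sequences that matched no listed RNA are given by length and value only.

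The alternatives were no TMM, DESeq2 1.42.0, limma 3.58.1 on log2(RPM + 1), other read minimums (1 read in at least 2 libraries, 50 reads in at least 3), thinning to the smallest total, other match lengths (10 nt, 14 nt), distinct sequences in place of reads, leaving out the 10 most abundant sequences, and leaving out each library in turn. Added after seeing the data were the test without the 5.8S rRNA end family, the longer RNA list, and the alternatives of results that were themselves added. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

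The tests were tried on simulated counts for the 5681 sequences, with 200 of them changed. With the fitted spread (median biological coefficient of variation 1.18), the test of the fractions against milk recovered 0% of sequences changed 2-fold, 4-fold or 8-fold. The test of 1 fraction recovered 0%, 0% and 3.23%. With a low spread of 0.2, added afterwards, the first test recovered 48.4%, 93.7% and 94.7%, and the second 13.6%, 65.1% and 81.7%, with 6 unchanged sequences called in each. Of the 39 parent RNAs, 12 were changed. At the fitted spread 3, 6 and 3 of them changed 2-fold, 4-fold and 8-fold, and 0%, 0% and 33.3% were recovered. At the low spread 3, 5 and 4 did, and 66.7%, 100% and 100% were recovered. Such small numbers give only rough percentages. At the spread of these libraries, changes up to 8-fold would thus mostly have been missed.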

Results

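RNA fragments of 8 to 15 nt were counted in 3 libraries of commercial cow's milk and in 1 library each of 4 milk fractions, 12k, 35k, 70k and 100k. The series title gives RNAs shorter than 15 nt in dairy milk as its subject. The milk libraries held 1658606 to 4572650 reads and the fractions 1817538 to 2560280. They listed 44623 to 72194 distinct sequences each and 229971 in all, of which 3869 occurred in all 7 libraries and 152873 (66.5%) in 1 library. Values of milk are means ± SD of 3 libraries. Each fraction is a single library with no replicate, and ± SD over fractions describes 4 different fractions.

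The first question was which short RNAs the milk contained. Most reads came from the 5' end of 5.8S rRNA, an RNA of the large ribosomal subunit. GACTCTTAGCGG, positions 2 to 13 of 5.8S rRNA, made up 46.0% ± 8.00 of the milk reads, and CGACTCTTAGCGG, positions 1 to 13, another 20.6% ± 4.88. With all related forms, this end family held 73.7% ± 2.96 of the milk reads and 61.3% to 78.2% of the reads of a fraction. The forms differed at the 5' side, while of the reads with the shared 11-nt core ACTCTTAGCGG 99.9% ended at its last base in milk 2, the library with the lowest such share. With the longer RNA list, which was made after the most abundant sequences had been seen, the next RNAs were 28S rRNA with 46419 ± 6359 RPM, 18S rRNA with 18371 ± 2546 RPM and lysine tRNA with 9642 ± 2581 RPM.

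Of the 10 most abundant milk sequences, 6 belonged to the 5.8S end family. Beside the 12-nt and 13-nt forms these were ACGACTCTTAGCGG with 18736 ± 325 RPM, AGACTCTTAGCGG with 8164 ± 1426 RPM, ACTCTTAGCGG with 6937 ± 692 RPM and GGACTCTTAGCGG with 6734 ± 1252 RPM. Counted from 1 at the 5' end of the 13-nt form, AGACTCTTAGCGG carried C1A and GGACTCTTAGCGG carried C1G. From 28S rRNA came CAGGACGGTGGCCA with 33801 ± 4745 RPM and GCAGGACGGTGGCCA with 6423 ± 1294 RPM. ACGTTGGGCGCC, positions 64 to 75 of lysine tRNA, reached 7105 ± 1773 RPM, and the 18S rRNA fragment GCAGCTAGGAATAA reached 6021 ± 1201 RPM. The 10 sequences held 64.2% to 79.6% of the reads of a library. The 3 leading sequences of each fraction were all among them. The 28S and 18S fragments were assigned through the longer list.

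The second question was how the fractions differed from milk as a whole. In length, 12-nt reads formed 51.1% ± 7.57 of the milk reads against 34.4% ± 15.1 over the fractions (exact permutation test, two-sided, p = 0.114, adjusted 0.514). Reads of 13 nt formed 26.7% ± 5.47 against 39.5% ± 16.3 (exact p = 0.286, adjusted 0.579). The gap lay in the 70k and 100k fractions, where 13-nt reads reached 46.5% and 59.1%, above each milk library, while the 12k and 35k fractions had 25.2% and 27.1%. Reads of 10 nt were above each milk library in 4 of 4 fractions, 4.38% ± 1.00 against 2.36% ± 0.360 (exact p = 0.0571, the smallest possible, adjusted 0.514). The difference of 2.02 points became 1.66 without the 10 most abundant sequences (exact p = 0.571) and -0.0517 with distinct sequences in place of reads. A large part of it in 12k and 35k lay in the leading unmatched 10-nt sequences. These held 13762 and 12455 RPM in 12k and 13219 and 12202 RPM in 35k. Over the 9 length measures no adjusted p passed.

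**Figure D1:**
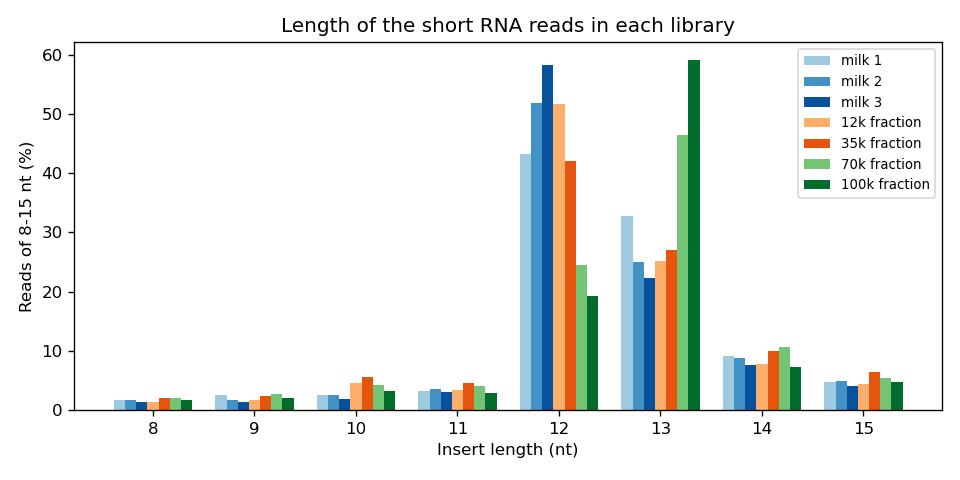
Share of the 8 to 15 nt reads (%) at each insert length (nt), with 1 bar per library. The 12-nt bar was the highest in the milk, 12k and 35k libraries and the 13-nt bar in the 70k (46.5%) and 100k (59.1%) fractions.

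The 2 leading forms of the 5.8S end followed the same pattern. The 12-nt form held 47.0% of the 12k reads, 35.7% of the 35k reads, 20.2% of the 70k reads and 15.8% of the 100k reads. The 13-nt form held 19.9%, 20.1%, 40.4% and 44.9% of them. The ratio of 13-nt to 12-nt reads was 0.690, 0.408 and 0.310 in milk 1, 2 and 3 and 0.424 in the 12k and 0.563 in the 35k fraction, but 2.00 in the 70k and 2.85 in the 100k fraction (4 fractions against milk, exact permutation test, two-sided, p = 0.286). The ratio of the 15-nt to the 14-nt form of the 28S fragment was also above milk in 70k and 100k, at 0.265 and 0.324 against at most 0.207. For the 18S fragment the ratio of CGCAGCTAGGAATAA to GCAGCTAGGAATAA went the other way, to 0.302 and 0.284 against at least 0.706 in milk.

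**Figure D2:**
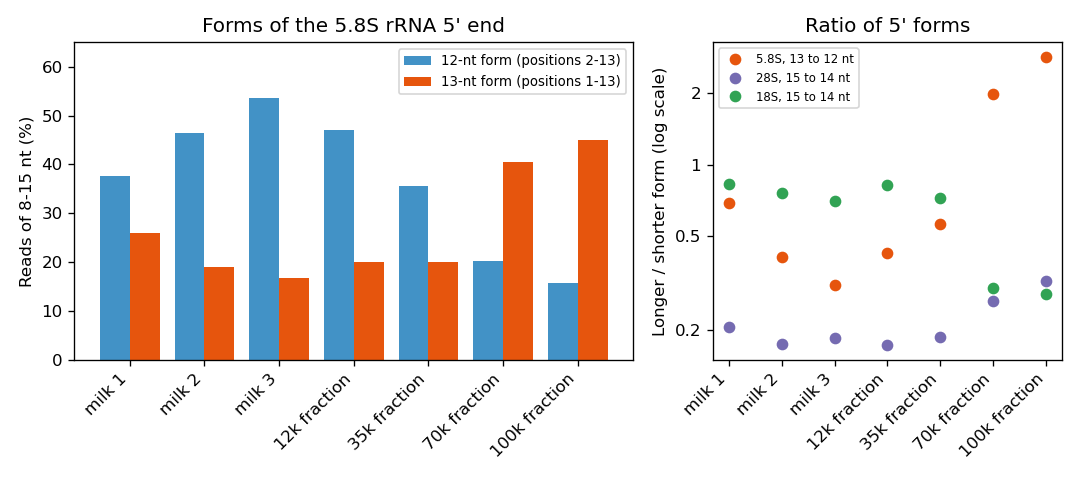
Left, share of reads (%) of the 12-nt and 13-nt forms of the 5.8S rRNA 5' end in each library; right, ratio of the longer to the shorter 5' form of the 5.8S, 28S and 18S rRNA fragments on a log scale. The 5.8S ratio was 2.00 in 70k and 2.85 in 100k and at most 0.690 in the other libraries, and the 18S ratio was lowest in the same fractions.

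Among the RNA classes, tRNA fragments made up 1.57% ± 0.346 of the milk reads and 0.749% ± 0.549 of the fractions' reads, below each milk library in 3 of 4 fractions (exact permutation test, two-sided, p = 0.114, adjusted 0.343). Listed rRNAs made up 67.1% ± 3.45 and 61.3% ± 4.58 (exact p = 0.171, adjusted 0.343), nearly all of it 5.8S rRNA. The match is exact, so 5' variants of the 5.8S end that the list lacked counted as unmatched. In 100k listed rRNAs held 60.8% of the reads, while the whole 5.8S end family held 78.2%, above each milk library. MicroRNA fragments were scarce, with 0.0625% ± 0.0259 in milk and 0.132% ± 0.120 over the fractions (exact p = 0.400, adjusted 0.480), and stood above each milk library in the 70k and 100k fractions. Y RNAs, small RNAs that bind the Ro60 protein, held 142 ± 51.9 RPM in milk and 139 ± 66.0 RPM in the fractions. U1 and the other small nuclear and 7SL RNAs held 41.4 ± 19.0 and 23.4 ± 18.6 RPM. Some 31.3% ± 3.62 of milk reads and 37.8% ± 4.40 of the fractions' reads matched no listed RNA or were ambiguous (exact p = 0.171). These shares include all reads under 12 nt, which were too short to be matched. The 10 most abundant sequences held 76.0% ± 3.19 and 72.8% ± 5.38 of the reads (exact p = 0.514) and the 100 most abundant 83.5% ± 2.66 and 80.2% ± 4.62 (exact p = 0.343). The share of G and C was 59.7% ± 0.295 in milk and 60.6% ± 0.643 in the fractions (exact p = 0.114, adjusted 0.286). Reads starting with C formed 30.2% ± 6.12 and 41.1% ± 13.8, and those starting with G formed 56.4% ± 7.66 and 41.5% ± 16.2 (exact p = 0.343 and 0.286). For C the difference reversed, to -1.20 points with distinct sequences in place of reads and to -3.18 points without the 10 most abundant sequences. For G it kept its direction under both.

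Sequence by sequence, 1 stretch of 28S rRNA was nearly lost from all 4 fractions. GGGAACGTGAGCTG fell from 223 ± 76.5 RPM in milk to 3.46 ± 3.00 RPM, a 64.4-fold difference (log2 fold change -6.19, SE 1.02, edgeR adjusted p = 0.0432). Its variant GGGAACGTGAGCTGG, longer by 1 base, fell from 255.5 ± 106.6 to 4.72 ± 3.56 RPM, 54.1-fold (log2 fold change -5.87, SE 1.04, edgeR adjusted p = 0.0485). Both were lower in 4 of 4 fractions than in each milk library, and both were assigned to 28S rRNA through the list made after the data were seen. They were the 2 sequences called by edgeR among 5681, of which 993 had an unadjusted p under 0.05, and no sequence was called higher. Both calls ended when any library was left out, without TMM, without the 5.8S end family, with a minimum of 1 read and after thinning, while the log2 fold changes stayed at -7.06 to -5.62 and -6.47 to -5.21 over the 15 alternatives. The count was 556 with DESeq2 (402 higher and 154 lower), 33 with limma and 1131 when the spread was taken from the milk libraries alone. The median log2 fold change over all sequences was -0.18 with TMM and -0.06 without it.

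Summed over each parent RNA, miR-10 was higher in the fractions, with 2 reads in the 3 milk libraries together and 141 in the 4 fractions, a ratio of 76.0 (95% counting interval 20.7 to 634). Its log2 fold change was 5.97 (SE 1.30, edgeR adjusted p = 0.0489), and all 4 fractions stood above each milk library. It was the 1 parent called of 39 tested, 2 having an unadjusted p under 0.05, and also the 1 member of 14 called in the broadly expressed list adjusted over the list alone. Of the 25 tested microRNA families, 22 had a positive fold change over the fractions together (21 with DESeq2), though 9 of 25 in 12k (7 with TMM, 12 with DESeq2) and 10 of 25 in 35k (9 with TMM) taken singly. Of the 6 tRNAs all had a negative one over the fractions together under each scaling, without passing the test, while taken singly 1 was positive in 12k (2 with DESeq2) and 3 in 35k (3 with DESeq2), and 0 with TMM. In the other lists edgeR called 0 of 4 rRNAs, 0 of 6 tRNAs, 0 of 7 epithelial and mammary families, 0 of 2 erythrocyte families, 0 of 1 leukocyte family, 0 of 1 family of other tissues, 0 of 2 Y RNAs, 0 of 1 small nuclear RNA and 0 of 1 adapter, also adjusted over the list alone. DESeq2 called 1 of the 39. The miR-10 call ended with TMM, with reads of 14 nt or more, and without milk 1, milk 2, milk 3, the 70k or the 100k fraction, with log2 fold changes of 5.40 to 6.70 over the 11 alternatives.

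The third question was how each fraction differed from milk, for parent RNAs by a test added after the data were seen. Each of these tests took its spread from the milk libraries alone and assumed that the single fraction varied like them, so its calls compare that library with milk. In the 70k and 100k libraries, fragments of lysine and histidine tRNA and of 5S rRNA were called lower. Lysine tRNA fell from 9642 ± 2581 RPM in milk to 506 RPM in 70k and 190.3 RPM in 100k, 19.0-fold and 50.7-fold (log2 fold change -4.25, SE 0.53, and -5.66, SE 0.58, edgeR adjusted p = 0.00109 and 0.000221). Histidine tRNA fell from 607 ± 260.4 RPM to 13.2 and 6.71 RPM (log2 fold change -5.52 and -6.49, edgeR adjusted p = 0.0126 and 0.00487). 5S rRNA, a further RNA of the large subunit, fell from 3983 ± 1604 RPM to 530 and 278 RPM (log2 fold change -2.91 and -3.84, edgeR adjusted p = 0.0191 and 0.00487). The same libraries held more miR-10, with 60 reads in 70k and 43 in 100k (ratios 154, interval 40.7 to 1297, and 103, interval 26.9 to 879, edgeR adjusted p = 0.0191 and 0.0314), and 70k held more miR-15/16, with 47.9 against 1.84 ± 1.09 RPM (log2 fold change 4.74, edgeR adjusted p = 0.0479). Without milk 2 all of these calls ended (edgeR adjusted p = 0.284 to 0.318 in 70k and 0.287 in 100k). Without milk 3 those of histidine tRNA (0.128 and 0.0752), 5S rRNA (0.178 and 0.0752) and miR-15/16 (0.0661) ended, and those of lysine tRNA and miR-10 stayed. With TMM those of miR-10 (0.0677 and 0.0587) and miR-15/16 (0.111) ended, and with DESeq2 that of miR-15/16 (0.199). The direction was kept throughout.

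The other tRNAs had negative fold changes in both fractions without passing over all parents. Glycine tRNA, mainly GCATTGGTGGTTCAG from its 5' end, held 4670 ± 740 RPM in milk, 3253 in 70k and 1946 in 100k. Glutamate tRNA held 518 ± 98.5, 209 and 137 RPM, and aspartate tRNA 195 ± 64.4, 91.3 and 84.1 RPM. Adjusted over the list alone, edgeR called 2 of 6 tRNAs in 70k and 3 of 6 in 100k, where over all parents it called 2 in each. For rRNA it called 1 of 4 in each fraction both ways. For the broadly expressed microRNAs it called 2 of 14 in 70k over all parents and 4 of 14 adjusted over the list alone, and 1 of 14 in 100k both ways. In the epithelial, erythrocyte, leukocyte, other tissue, Y RNA and small nuclear lists it called 0 both ways.

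Of the 25 microRNA families, 21 had positive fold changes in 70k (18 with DESeq2) and 17 in 100k (20 with TMM). Broadly expressed let-7 stood at 189 ± 47.3 RPM in milk, 786 in 70k and 291 in 100k. In the epithelial and mammary list, 4 of 7 tested families were higher and 3 lower in each of these fractions. Of these, miR-183 stood at 138 ± 108, 900 and 338 RPM, and miR-30 at 23.4 ± 2.70, 49.5 and 43.3 RPM, while the miR-148 family was lower with 61.9 ± 6.53, 12.7 and 5.16 RPM, as were miR-141/200a (log2 fold change -0.42 and -1.34) and miR-99/100 (-0.75 and -0.58). Broadly expressed miR-191 had 42.8 ± 45.7, 490 and 221.8 RPM. None of these passed over all parents. In milk 1 several of these microRNAs also stood above milk 2 and milk 3, miR-183 at 260.5 against 96.1 and 56.4 RPM and miR-191 at 94.7 against 25.4 and 8.31 RPM. Lists of blood cell microRNAs also had higher values in 70k and 100k, with none of their 3 tested families called, the erythrocyte list at 31.4 ± 41.4 RPM in milk (79.0, 11.7 and 3.50 RPM in milk 1, 2 and 3) against 241 and 109 RPM and the leukocyte list at 8.09 ± 5.20 against 47.9 and 28.4 RPM. The list of other tissues had 2.97 ± 2.30 RPM in milk and 42.4 and 15.5 RPM in these fractions. Plant microRNAs had 0 reads in all 7 libraries, which allows up to 0.656 to 1.81 RPM, and kit adapters at most 12.6 RPM.

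**Figure D3:**
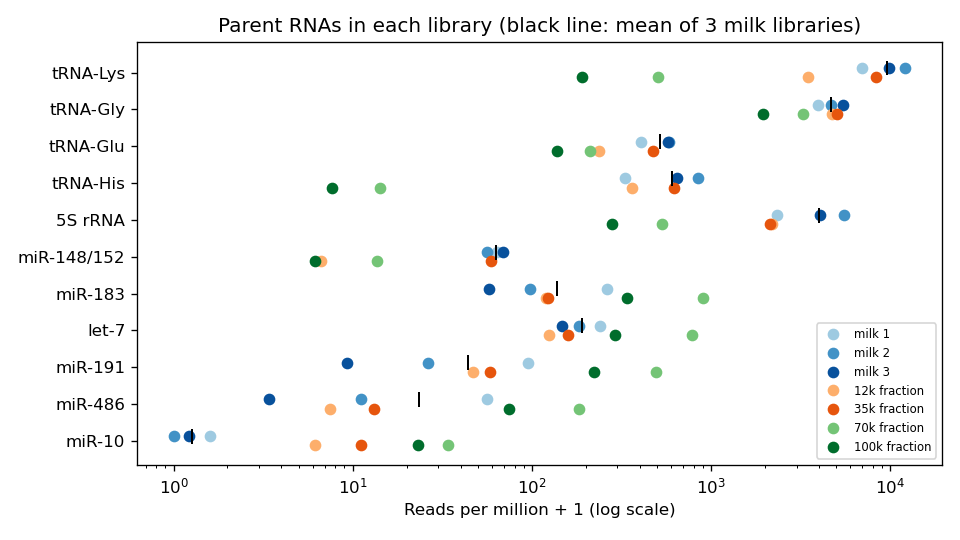
RPM + 1 (log scale) of 11 parent RNAs, 1 point per library, with a black line at the mean of the 3 milk libraries. Lysine and histidine tRNA and 5S rRNA were lowest in the 70k and 100k fractions, where lysine tRNA had 506 and 190.3 RPM, and miR-10 was above milk in all 4 fractions.

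In the 12k and 35k fractions edgeR called 0 of 39 parent RNAs, with 3 and 2 at an unadjusted p under 0.05 and 0 with DESeq2. Lysine tRNA had 3469 and 8338 RPM there, 5S rRNA 2198 and 2129 RPM, and tRNAs as a class 8871 and 14598 RPM against 15667 ± 3464 RPM in milk. The broad microRNA list had 225 and 289 RPM against 287 ± 116 RPM in milk, and the epithelial list 168 and 268 RPM against 295 ± 106 RPM. The erythrocyte list had 15.6 and 15.2 RPM and the leukocyte list 1.73 and 10.9 RPM. The parent calls in 70k and 100k ended without milk 2 (edgeR 0 and 0, with 4 and 6 at an unadjusted p under 0.05), and numbered 12 and 9 without milk 1, 2 and 2 without milk 3, 3 and 3 with TMM, all lower, and 11 (1 higher, 10 lower) and 6 (1 higher, 5 lower) with DESeq2.

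Among single sequences, 62.9% of those called lower in 70k and 60.2% in 100k matched no listed RNA, against 89.0% of all 5681 tested, and the rest were mainly fragments of tRNA and rRNA. Of 35 sequences called lower in 70k, 22 were unmatched, 7 matched tRNA, 5 rRNA and 1 the 5.8S end family. Of 103 in 100k, 62 were unmatched, 24 matched tRNA, 11 rRNA, 5 the end family and 1 a Y RNA. The calls included 14 and 32 sequences under 12 nt, too short to be matched. Without milk 2 edgeR called 0 lower in each, and without milk 3 it called 33 and 169. Of all 5681 tested sequences 187 matched tRNA, 247 matched rRNA and 2640 were under 12 nt, and enrichment was not tested. ACGTTGGGCGCC of lysine tRNA fell from 7105 ± 1773 RPM to 246 and 74.3 RPM (edgeR adjusted p = 0.0294 and 0.00238). Chosen after their values were seen, TGGTTAGTACTCTGC of histidine tRNA fell from 364 ± 189 RPM to 2 reads in 70k and 2.58 RPM in 100k (edgeR adjusted p = 0.0229 and 0.00793) and GGTGCTGTAGGC of 5S rRNA from 1153 ± 622 to 12.1 and 2.06 RPM (edgeR adjusted p = 0.0229 and 0.00115). ATGGCACTGGTAGA of miR-183, also chosen so, rose from 2.05 ± 1.26 to 101 and 59.3 RPM (edgeR adjusted p = 0.0449 and 0.0165).

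The 100k fraction had 120 sequences called higher, of which 101 matched no listed RNA, 45 of the 120 being under 12 nt, and 17 were 5' variants of the 5.8S end. Without milk 3 it had 35 higher and 169 lower, with the 1-read minimum 10 and 60, and without milk 2 it had 1 higher. AGACTCTTAGCGG rose from 8164 ± 1426 to 44836 RPM (log2 fold change 2.66, SE 0.71, edgeR adjusted p = 0.0279). Chosen after its values were seen, ATACTCTTAGCGG, which carries C1A and G2T, rose from 50.9 ± 51.6 to 26390 RPM (edgeR adjusted p = 2.63e-09). AAGGACGGTGGCCA, which is the 28S fragment CAGGACGGTGGCCA with C1A counted from its own 5' end, rose from 55.2 ± 33.4 to 2611 RPM (edgeR adjusted p = 2.55e-05) and was chosen in the same way.

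In 12k and 35k, 91 and 127 sequences were called higher, and 90 and 125 of these matched no listed RNA, of which sequences under 12 nt, 41 and 54 of the calls, were too short to be matched. The numbers called higher by edgeR were 0 and 0 without milk 2 (251 and 305 in either direction at an unadjusted p under 0.05), 25 and 44 without milk 1 and 10 and 18 without TMM. Of the unmatched ones 82 were higher in both, and by this selection they held 4.90% and 5.40% of the reads against 0.167% to 0.240% in milk, 0.640% in 70k and 0.679% in 100k. The most abundant was 10 nt long, with 13762 and 13219 RPM against 727 ± 218 RPM in milk. The next, also of 10 nt, had 12455 and 12202 RPM against 478 ± 138 RPM. Of rRNA, AGGGACGGCCGG, assigned to 18S rRNA through the longer list and chosen after its values were seen, rose from 47.1 ± 14.8 to 401 and 596 RPM (edgeR adjusted p = 0.0498 and 0.0275).

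In all, edgeR called 95 sequences in 12k (91 higher, 4 lower), 134 in 35k (127 and 7), 64 in 70k (29 and 35) and 223 in 100k (120 and 103) of 5681. Without milk 2 these counts were 0, 0, 0 and 1, with 251, 305, 477 and 514 at an unadjusted p under 0.05, and without milk 1 they were 27, 48, 493 and 555. Without milk 3, 70k had 34, of which 1 was higher, and 100k had 204, of which 35 were higher. With the file totals and no TMM they were 10, 18, 0 and 0, with 665, 748, 1268 and 1320 at an unadjusted p under 0.05, against 162 (123 higher), 231 (162 higher), 766 (307 higher) and 807 (224 higher) with DESeq2. Of the sequences with 13 nt or more and 10 to 60 reads, milk 2 listed 98.5% of those of milk 3, and milk 3 listed 40.0% of those of milk 2.

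The last question was how alike the libraries were. The 70k and 100k fractions were the closest pair, with a Spearman correlation of 0.824 across the 5681 sequences, which are not independent replicates. Milk libraries correlated at 0.386 to 0.644 with each other and at -0.057 to 0.367 with the fractions, and the 12k and 35k fractions at 0.498. A milk library shared a median of 36.2% of its distinct sequences with another milk library, and a fraction shared 24.2% with a milk library. The shared sequences carried 92.8% to 99.2% and 86.9% to 93.7% of the reads.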

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

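The tests of a first base that differs in the 100k library, of milk RNA sampled by both libraries, of milk 2 in milk 1 and of the 13-nt form were chosen after the result was seen. The following 3 measures of the 100k fraction stood apart from the other fractions.

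In the 100k fraction, forms with the 11-nt core other than the 12-nt and 13-nt forms reached 16.04% of the reads, against 4.37% to 5.12% in the other fractions and 5.54% ± 0.479 in milk. AGACTCTTAGCGG reached 44836 RPM there and at most 8643 RPM in the other fractions. Reads with an uncalled base reached 0.126% there and 0.0426% to 0.0444% in the other fractions, 2.80 times the highest milk library. Among 49 results tested in this way, these 3 stood apart, all in 100k, where chance alone marks about 1 in 20.

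For the 5' variants with a changed first base and no other change, base calls or ligation at the first base that differ in the 100k library are a candidate explanation. Over 11 other sequences starting with C, the median share read with A was 15.5% in 100k, 25.8 times that of the highest milk library, and all 11 exceeded 5% in 100k. The highest share was 41.3%. In 100k the 5.8S form with C1A and G2T, at 26390 RPM, outnumbered the form with G2T alone. The latter had 17540 RPM there and 2675 ± 3549 RPM in milk. A first-base change at the level of the 11 sequences does not account for this. The change at the second base was not tested. Failed base calls at the first 2 positions could not be weighed. The bound set beforehand was a poor one, because the uncalled base lay at position 1 or 2 in 100% of such reads of each milk library, which left a ratio of 0.998 with no room to rise. A true difference of RNA ends in the 100k fraction stays open as untested, since this fraction has 1 library.

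A second pattern was the excess of the 13-nt over the 12-nt form of the 5.8S end in 70k and 100k, with ratios of 2.00 and 2.85 against at most 0.690 in milk. A change at the 5' ends of all abundant RNAs alike predicted higher ratios for both the 28S and the 18S fragment. The 28S ratio rose to 0.265 in 70k and 0.324 in 100k against at most 0.207 in milk. The higher 18S ratio in these fractions was 0.427 times the lowest milk ratio. The counted forms thus did not change alike. Their longer forms have 15 nt, the top of the listed window, so ends extended further were not counted and the ratios cannot decide. The first-base change of the 100k library takes reads from the 13-nt form, which starts with C, and so lowers its ratio. With the reads of another first base returned to both forms, the ratio was 2.04 in 70k and 3.13 in 100k. In milk it was at most 0.713. Since returning reads could hardly lower the ratio, the return decides nothing by itself. In 70k the change was not seen, with a median share read with A of 0.376% against 0.188% to 0.599% in milk. A ligation that favours some ends was not tested by these ratios. A separate preparation of the 70k and 100k libraries cannot be told apart from the fractions themselves, because both libraries, with a correlation of 0.824, also differ from the rest by fraction. Milk 1, which is no fraction, correlated at 0.263 and 0.232 with 70k and 100k, and at 0.337 and 0.308 with 12k and 35k. Milk 2 and milk 3 correlated at -0.057 to 0.001 with 70k and 100k. Whether milk 1 shares a trait of these libraries apart from the fraction was not tested. A difference between the fractions' RNA stays open as untested.

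The last pattern concerned the milk libraries, for which the design gives no biological contrast and none was tested. Of the milk 3 sequences of at least 13 nt with 10 to 60 reads, 98.5% were listed in milk 2. Of such milk 2 sequences only 40.0% were listed in milk 3, which had the most reads. That 40.0% cannot decide on milk RNA that both libraries sampled, because milk 2 may also hold sequences of its own. Reads carried from milk 3 into milk 2 at a constant share remain a candidate explanation. Over sequences found in no other library, the median ratio of milk 2 to milk 3 reads was 0.2 at 10 to 30 reads. It was 0.167 at 31 to 60 reads, a 1.2-fold difference that lay narrowly inside the bound set beforehand. Shared RNA at a steady lower level in milk 2 would give a like ratio, so the ratio does not separate the 2 explanations. For milk 2 in milk 1 the shares were 82.9% and, in reverse, 50.9%, a ratio of 1.63 that decided nothing. Carried reads would make the milk libraries less independent, narrow the spread behind each test of a single fraction, and raise the sharing (36.2%) and the correlation (0.644 for milk 2 and milk 3) among milk libraries.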

How the results depend on the processing

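The alternative without the 5.8S rRNA end family, the longer RNA list, and the tests of single fractions on parent RNAs with their alternatives were chosen after the result was seen. No paired analysis was possible because each fraction has 1 library and shares only the number 1 with milk. Scaling by the totals behind the authors' RPM was not run, since these equal the file totals. Unless the construction shows it, the cause was not tested.

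Of the sequences, 2 differed between the fractions and milk. edgeR called 0 without TMM (913 at an unadjusted p under 0.05), 0 with at least 1 read in at least 2 libraries (12724), 0 after thinning (697), 0 without the 5.8S end family (875) and 0 to 0 on leaving out each library (440 to 993). DESeq2 called 556 (402 higher, 154 lower), limma 33 (16 and 17), the 50-read minimum 25 (22 and 3, with fewer sequences tested) and 5 group means 1131 (210 and 921), where the differences between fractions no longer counted as spread.

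For the 12k fraction (95 called), the count was 10 without TMM, 162 with DESeq2, 30 and 32 at minimums of 1 and 50 reads, and 0 to 80 on leaving out each milk library. For 35k (134) it was 18, 231, 43 and 45, and 0 to 105. For 70k (64) it was 0, 766, 51 (0 higher) and 302, and 0 to 493. For 100k (223) it was 0, 807, 70 (10 higher) and 372 (120 higher), and 1 to 555, with 204 (35 higher) without milk 3. DESeq2 split its calls into 123 higher and 39 lower for 12k, 162 and 69 for 35k, 307 and 459 for 70k, and 224 and 583 for 100k. Among the runs that left out a milk library, the lowest count in all 4 was that without milk 2.

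Among parent RNAs, fractions against milk (1 called), edgeR called 0 with TMM (3 at an unadjusted p under 0.05), 0 with reads of 14 nt or more (2) and 0 to 2 on leaving out each library, and DESeq2 called 1. Leaving out each milk library gave 0 to 2 for 12k, 0 to 1 for 35k, 0 to 12 for 70k (5 called) and 0 to 9 for 100k (4 called). For 70k TMM gave 3 and DESeq2 11. GGGAACGTGAGCTG, its variant and the parents called kept their direction under every alternative run on them, and the sequences named in single fractions were followed only by their counts. Over these alternatives, the adjusted p ranged from 9.25e-09 to 0.410 for GGGAACGTGAGCTG and from 0.000558 to 0.250 for miR-10, with log2 fold changes of -7.06 to -5.62 and 5.40 to 6.70.

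Counting distinct sequences in place of reads reversed the fractions minus milk difference, in percentage points, at 8 nt (-0.477), 9 nt (-0.0548), 10 nt (-0.0517), 11 nt (-0.0559), first base C (-1.20) and first base T (-1.14). Leaving out the 10 most abundant sequences, which include the 5.8S forms, reversed it at 13 nt (-0.552), 15 nt (-1.64), mean length (-0.105 nt), first base C (-3.18) and first base T (-0.544). Leaving out single libraries took 14 nt from -0.108 to 0.983 and Y RNA from -0.00334 to 0.00235. Without milk 3 the value at 14 nt was -0.0188. Y RNA was 0.0413 with reads of 10 nt or more, 0.00172 without 12k and 0.000786 without 100k. Values that moved past the spread or over 1.5 times in a count numbered 57 for the main results, and those that reversed 8. In 161 for the main results and 119 for single lengths, bases and named items, values kept their direction and side of the threshold or moved within the spread, and in 47 for named items they kept direction but no longer passed. Within that spread, leaving out 1 library still changed some differences over 1.5 times. The microRNA share went from 0.0699 to 0.0124 without 70k, 13 nt from 12.8 to 6.23, mean length from 0.0940 to 0.0300 nt, first base G from -14.9 to -9.20 and the 13-nt to 12-nt ratio from 0.989 to 0.525 without 100k. G and C went from 0.820 to 0.522 without 70k, and first base C from 10.9 to 7.08 without 70k and 6.73 without 100k. Without 35k the 10 and 100 most abundant sequences went from -3.19 to -0.814 and -3.31 to -1.54 and the 5.8S end family from -3.75 to -0.864, and without milk 3 they went to -1.40, -1.78 and -2.04. The family went to -6.49 without 100k, mean length to 0.148 nt without 12k, and small nuclear and 7SL RNA from -0.00180 to -0.000716 without milk 2 and -0.00120 without 12k. Depth limited a count of 0 to 0.656 to 1.81 RPM.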

Other observations

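The test of bacterial RNA was planned before its result was seen, and the comparisons with other splits of the libraries were chosen after it.

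Segments of RNAs added after the most abundant unmatched sequences had been seen gave further tRNAs, which were not tested. Cysteine tRNA held 2463 ± 942 RPM in milk (n = 3), 2930 in 12k, 2767 in 35k, 272 in 70k and 70.2 in 100k. Serine tRNA held 984 ± 303 RPM in milk, 475 in 12k, 989 in 35k, 114 in 70k and 94.9 in 100k. Alanine tRNA held 1061 ± 353 RPM in milk, 447 in 12k, 877 in 35k, 49.5 in 70k and 33.0 in 100k. With the added segments, 18S rRNA held 18371 ± 2546 RPM in milk, 6338 in 70k and 3095 in 100k, and 28S rRNA 46419 ± 6359 RPM in milk, 72536 in 70k and 29604 in 100k. Classes counted with these segments were 73.5% ± 3.05 rRNA and 2.29% ± 0.565 tRNA in milk and 66.9% ± 4.60 and 1.09% ± 0.835 in the fractions, partly so by construction. Neither a list nor the 5.8S end family covered 17.0% ± 2.70 of the milk reads and 22.9% ± 5.32 of the fractions' reads. These shares include the reads under 12 nt outside the end family, which were too short to be matched.

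The number of sequences with a given read count had a second peak in 4 libraries, at 26 reads in milk 2, 28 in milk 3, 10 in 12k and 18 in 35k, and none was found in milk 1, 70k and 100k by the rule used, which was set after the distributions were seen. Taken by length, the peak lay at 26 to 30 reads in milk 3 and 15 to 21 in 35k, but at 22 to 52 in milk 2 and 9 to 40 in 12k.

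Bacterial RNA was a hypothesis for the unmatched sequences that rose in 12k and 35k. The share of reads, 12 nt or longer, that matched bacterial ribosomal and transfer RNA segments averaged 1.97 times the highest milk library over these fractions, 1.02 times in 12k and 2.92 times in 35k. The prediction of a rise in each was not met, nor was the bound that would have excluded it. The unmatched sequences matched none of these segments by construction. The share of other reads could therefore not decide their source, which stays open.

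Of the 35 splits of the 7 libraries into 3 and 4, only 1, the real one, gave 2 sequences, and the highest other gave 1. That rests on counting the sequences apart, but both are nested in 1 stretch. Counted once they tie with the 1 sequence of the split of milk 1, milk 2 and 100k against the rest, so chance cannot be excluded. On leaving out any single library edgeR called 0 (440 to 993 at an unadjusted p under 0.05). For parent RNAs, 4 of the 35 splits gave as many as the real 1, so chance cannot be excluded. The highest other split called 8, setting milk 1 with 70k and 100k against the rest, which points to a structure of the libraries other than milk against fractions.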
